A study of Mus musculus with 12 samples.

How the data were processed

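RNA was measured by mRNA sequencing of mouse intestinal tumour organoids, which are cultures of epithelial cells grown in Matrigel in DMEM/F12 with EGF, Noggin, B27 and N2. The cultures carried alleles driven by villinCreER in 2 genotypes. AKPT is Apc fl/fl, Kras G12D/+, Trp53 fl/fl and TrgfbrI fl/fl, of which the last was read as Tgfbr1, a receptor of TGF-beta. KPN is Kras G12D/+, Trp53 fl/fl and Rosa26 N1icd/+, which expresses the intracellular domain of Notch1. Organoids of each genotype were left untreated (DMSO vehicle in the treatment protocol) or given the bile acid deoxycholic acid (DCA) for 48 h. The sources give the dose of DCA in 2 units: the sample labels state 50 µM, and the treatment protocol states 50 mM from a stock of 185 mM. The dose is given here as the labels state it, and no comparison depends on its value.

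The deposited table holds raw read counts per Ensembl gene ID as the authors made them, for 56923 genes in 12 libraries, with no normalisation; the values are whole numbers. The authors' notes name HISAT2, SAMtools and HTSeq and the genome build GRCm39, without versions. The annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here. Libraries were prepared with a TruSeq mRNA kit and sequenced on a NovaSeq. Each group had 3 libraries, which the labels call independent replicates, and the totals ran from 22146335 to 24461409 counts per library. Gene symbols were taken from a GENCODE annotation of the previous mouse genome build, matched by Ensembl gene ID, and 52073 IDs (91.5%) had one. No genome positions are given, because that annotation is on another build. Of the tested genes 256 had no symbol and 3 symbols were shared by more than 1 ID, in which case the ID with more counts kept the symbol.

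Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, and plots were made with matplotlib 3.10.9 in Python 3.11.15. Genes were kept by filterByExpr with the 4 groups (minimum count 10, minimum total 15), which left 14541, and library sizes were scaled by TMM. A quasi-likelihood negative binomial model (glmQLFit with robust estimation) was fitted to all 12 libraries with 1 factor of group, and each contrast was tested with a two-sided quasi-likelihood F-test. The p-values were adjusted by the Benjamini-Hochberg method over the 14541 genes, and a gene was called changed at an adjusted p under 0.05. The common biological coefficient of variation was 0.0669. There were 5 comparisons: DCA against untreated in AKPT, the same in KPN, KPN against AKPT untreated, KPN against AKPT with DCA, and the difference between the DCA responses (KPN minus AKPT). Levels are CPM from edgeR (counts scaled to the effective library size after TMM), given as mean ± SD over 3 libraries. Log2 fold changes carry an approximate standard error (SE), which is the absolute log2 fold change divided by the square root of its F statistic. It rests on the fit to all 12 libraries, and an n beside it is the number of libraries per group. Exact counting intervals and floors cover counting error only, and a count of 0 was given a floor of 3 counts per library. Bootstrap intervals were drawn over genes and do not cover the spread between libraries. Principal components were taken on log2 CPM with a prior count of 2.

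Before the data were examined, 31 gene lists with 628 entries were fixed, along with the comparisons, the tests, the alternatives and the rule for naming genes. The lists covered bile acid response, cholesterol synthesis, fatty acid oxidation and PPAR targets, glycolysis and hypoxia response, oxidative phosphorylation, endoplasmic reticulum stress and integrated stress response, NRF2 oxidative stress response, p53 targets and DNA damage, G2/M proliferation, DNA replication, NF-kB and inflammatory mediators, interferon response, Wnt target genes, Notch target genes, TGF-beta target genes, RAS/MAPK output, YAP/TAZ targets, epithelial-mesenchymal transition, matrix proteases and invasion, immediate early and heat shock genes, fetal-like and regenerative epithelium, intestinal stem cell markers, and markers of enterocytes, goblet cells, Paneth and deep crypt secretory cells, enteroendocrine cells, tuft cells, gastric and squamous epithelium, immune cells, endothelium and fibroblasts. A list was tested with camera in limma, which compares its genes with all others, at a preset inter-gene correlation of 0.01, and adjusted over 30 lists within a comparison. The same test with a correlation estimated for each list, and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were run as alternatives. Calls within a list are also given as adjusted over the list alone. The immediate early and heat shock list was fixed to stand for RNA handling and quality.

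Genes were named by a fixed rule. For each DCA comparison and for the untreated genotypes these were the 6 highest and the 6 lowest called genes with at least 5 CPM in the higher group and groups that did not overlap, without predicted genes; chance gives 10% of genes such groups with 3 libraries against 3. With DCA, the genotype comparison took the 3 highest and 3 lowest. The difference took the 5 highest and 5 lowest called genes with 5 CPM in at least 1 group. From each list described, up to 3 called members with the smallest adjusted p were eligible, or the 2 most abundant members where none was called. The 5 genes in the genotypes (Apc, Trp53, Tgfbr1, Kras and Notch1) were always named, as were Nr1h4, Gpbar1, Slc51a, Slc51b, Lgr5, Mki67 and Hes1 in the DCA comparisons.

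The alternatives were RLE factors or library totals in place of TMM, no filter on low counts, a filter at 1 CPM in 3 libraries, the 2 compared groups alone in the fit, DESeq2 1.42.0 (Wald test), the replicate number as a block, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and leaving out each library in turn. Whether replicate numbers pair the libraries was checked by correlating each library's deviations from its group mean between groups. Libraries with the same number correlated at -0.0539 to 0.210 in AKPT and -0.130 to 0.0245 in KPN, and 3 of 6 and 2 of 6 libraries correlated best with their own number, so the numbers were not taken as pairs. Counts of replicates differed by more than counting error, with a chi-square per degree of freedom of 4.93 to 13.7 over genes with at least 50 counts.

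The procedure was tested on simulated data with known changes in 14541 genes. In a simulated DCA comparison in AKPT it recovered 36.7% of genes changed 1.25-fold, 80.0% of those changed 1.5-fold, 90.0% of those changed 2-fold and 96.0% of those changed 3-fold, and 3.41% of calls were false. In KPN the recovered shares were 55.1%, 86.0%, 94.0% and 100%, and 5.15% of calls were false. For the untreated genotypes they were 46.0%, 86.0%, 90.0% and 100%, with 8.72% false. A list shifted by 0.3 on the log2 scale was called in each of these. Of the other 29 lists 1, 0 and 1 were called. The simulated genes were drawn independently, so these list calls do not test the preset inter-gene correlation. In the measured data the estimated correlation exceeded the preset for some lists, such as 0.298 for cholesterol synthesis with DCA in AKPT. That list was called there with a median of -0.062, and recovery of list shifts smaller than 0.3 was not tested.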

Results

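The series asked how the genotype of an intestinal tumour shapes its response to deoxycholic acid (DCA), a bile acid, against a background of high-fat diet and recurrence of colon cancer after surgery. Messenger RNA was counted in tumour organoids of 2 genotypes, AKPT and KPN, each untreated and after 48 h with DCA at a labelled 50 µM, with 3 independent replicates in each of the 4 groups. Counts per library ran from 23432937 to 23697414 in untreated AKPT and from 23956146 to 24461409 in AKPT with DCA. In KPN they ran from 22146335 to 23556909 untreated and from 22762246 to 23833485 with DCA. The reads fell on 14541 genes with enough counts to test.

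The 2 genotypes lay apart on the main axis of the data. No organoid line or mouse of origin entered the comparisons, so differences between genotypes cannot be told apart from differences between lines. The first principal component held 58.2% of the variance and parted AKPT from KPN. Its means were -41.7 ± 6.61 in untreated AKPT, -26.4 ± 5.01 in AKPT with DCA, 34.6 ± 1.65 in untreated KPN and 33.5 ± 2.16 in KPN with DCA (SD, n = 3). Among the untreated AKPT libraries, replicate 1 lay nearest to those with DCA, at -34.5. The mitochondrial share of counts was 0.893% ± 0.0147 in untreated AKPT and 0.689% ± 0.135 in AKPT with DCA (SD, n = 3). The exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 can give. In KPN it was 0.836% ± 0.0882 and 0.769% ± 0.0382 (exact permutation p = 0.4). The share of ribosomal protein genes was 4.55% ± 0.130 in untreated AKPT and 5.23% ± 0.342 in untreated KPN (exact permutation p = 0.1). Over the 4 pairwise comparisons and 4 such measures, the lowest Benjamini-Hochberg adjusted value was 0.267.

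**Figure D1:**
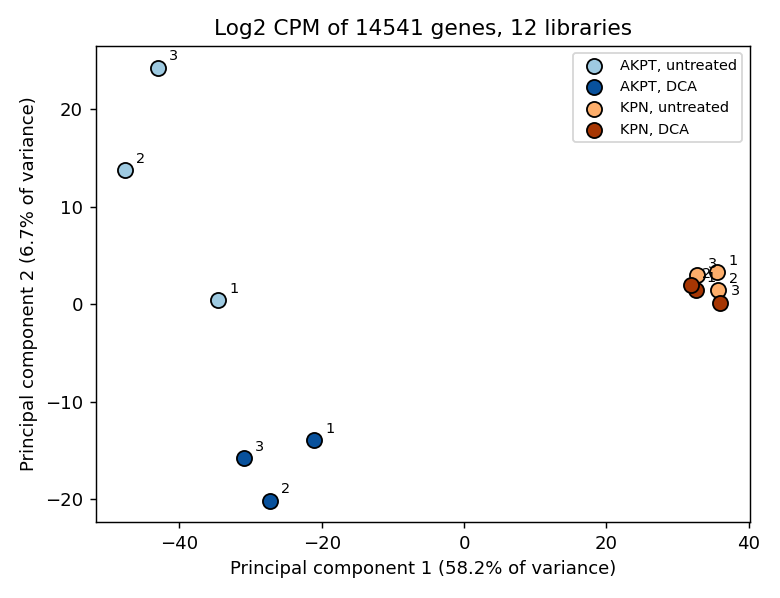
Principal components 1 and 2 of log2 CPM over 14541 genes (axes in component units, with the share of variance in percent); each point is 1 of 12 libraries, colored by group and numbered by replicate. AKPT and KPN lie apart on component 1, and the AKPT libraries with DCA have less negative values (mean -26.4) than the untreated ones (mean -41.7).

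The 5 genes altered in the genotypes were all expressed. In untreated organoids Apc, the Wnt pathway scaffold, stood at 159 ± 3.81 CPM in AKPT and 140 ± 19.5 in KPN. Tgfbr1 stood at 48.6 ± 2.39 and 56.6 ± 7.80, Notch1 at 72.0 ± 1.10 and 64.0 ± 4.22, Kras at 119 ± 7.33 and 129 ± 9.50, and Trp53 at 6.01 ± 0.587 and 6.22 ± 0.606 (SD, n = 3). In libraries labelled KPN, untreated Notch1 was lower (log2 fold change -0.17, SE 0.0578, adjusted p = 0.0166), as was Apc (-0.18, SE 0.0677, adjusted p = 0.0264), and Tgfbr1 was higher (0.22, SE 0.0746, adjusted p = 0.0158). Kras (0.12, adjusted p = 0.104) and Trp53 (0.05, adjusted p = 0.801) did not pass. Without untreated AKPT replicate 2 the adjusted p became 0.0693 for Notch1, 0.116 for Apc and 0.0781 for Tgfbr1. Without untreated KPN replicate 1 it became 0.120 for Notch1, 0.290 for Apc and 0.0233 for Kras. Without untreated AKPT replicate 1 it was 0.0341 for Kras. Tgfbr1 also lost its call without untreated KPN replicate 2 (adjusted p = 0.0632) and replicate 3 (0.121). With library totals in place of TMM factors the adjusted p was 0.0947 for Notch1, 0.117 for Apc and 0.0236 for Kras. With DCA only Tgfbr1 of the 5 differed between the genotypes (0.27, SE 0.0740, adjusted p = 0.00488). DCA changed none of the 5 in AKPT (log2 -0.12 to 0.06, lowest adjusted p 0.238 for Kras) or in KPN (-0.18 to 0.13, lowest adjusted p 0.418 for Kras). Counts summed over a whole gene do not show the loss of a floxed exon or the origin of a Notch1 fragment, so these values do not check the labels.

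In AKPT organoids, genes of glycolysis and the hypoxia response rose together with DCA. Of the 22 measured members of that list 16 rose and 0 fell, and 19 rose when adjusted over the list alone (camera adjusted p = 1.04e-30; adjusted p = 0.102 with an estimated correlation). Pfkl (ENSMUSG00000020277), a subunit of phosphofructokinase, went from 251 ± 21.4 to 358 ± 16.4 CPM (1.43-fold, SD, n = 3; adjusted p = 2.01e-05). The glycolytic isomerase Gpi1 rose 1.32-fold (adjusted p = 6.83e-05), and P4ha1, a collagen prolyl hydroxylase, rose 1.41-fold (adjusted p = 0.00011). Inflammatory mediators fell: of 22 genes of the NF-kB list 9 fell and 1 rose, or 10 and 1 when adjusted over the list alone (adjusted p = 1.54e-06; adjusted p = 0.377 with an estimated correlation). The neutrophil chemokine Cxcl1 (ENSMUSG00000029380) went from 38.8 ± 4.11 to 25.1 ± 1.84 CPM (n = 3; 1.55-fold lower, adjusted p = 6.83e-05). Cxcl2 was 1.76-fold lower (adjusted p = 0.000606), and the cytokine Il1a was 1.27-fold lower (adjusted p = 0.00077).

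DCA changed 903 genes in AKPT, 468 higher and 435 lower, by a median of 0.342 on the log2 scale in size; 76 of them changed at least 2-fold. Some genes with less than 5 CPM rose more, such as Bnip3 (log2 2.13, adjusted p = 0.000504). Among genes with at least 5 CPM and groups that did not overlap, the largest rise belonged to Cyp2s1, a cytochrome P450, from 13.7 ± 4.71 to 30.8 ± 6.58 CPM (log2 1.17, SE 0.244, adjusted p = 0.0288). Ndrg1, a stress gene induced by hypoxia, rose by 1.09 (SE 0.241, adjusted p = 0.0370) and Fbln2 (ENSMUSG00000064080), which encodes the matrix protein fibulin-2, by 1.07 (SE 0.162, adjusted p = 0.00569; from 21.0 ± 5.67 to 44.0 ± 5.78 CPM). Kbtbd11 (1.05, adjusted p = 0.0156), Zfp395 (1.03, adjusted p = 0.0157) and Acacb, an acetyl-CoA carboxylase (0.97, adjusted p = 0.0169), followed. By the same limits the largest falls were those of Sprr1b, a protein of the cornified envelope (log2 -2.61, SE 0.515; from 5.98 ± 3.25 to 0.974 ± 0.347 CPM), the galactosyltransferase B3galt5 (-2.59, SE 0.493; 6.03-fold lower). They were followed by the small GTPase Rab15 (-2.50, SE 0.552), the matrix proteoglycan Prelp (-2.50, SE 0.534), the transporter Slco4a1 (-2.12, SE 0.512) and the metalloproteinase inhibitor Timp3 (-1.90, SE 0.423), with adjusted p from 0.0146 to 0.0496 (SD and SE, n = 3). Of these 12 genes, Fbln2 kept its call without each of the 6 libraries in turn. Without DCA replicate 1 the other 11 lost theirs (adjusted p = 0.0612 to 0.157), and without DCA replicate 2 all but Fbln2 and Kbtbd11 did (0.0600 to 0.162). Without untreated replicate 3 the call was lost by all but Fbln2, Sprr1b and Prelp (0.0530 to 0.129). Without untreated replicate 2 it was lost by Ndrg1, Acacb and all 6 that fell (0.0539 to 0.130), and without DCA replicate 3 by 5 of the 6 that fell, Sprr1b excepted (0.0564 to 0.117). With RLE factors Slco4a1 lost its call (adjusted p = 0.0503), and with the replicate number as a block Ndrg1 (0.0806), Rab15 (0.053) and Slco4a1 (0.0963) did.

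The count of 903 moved with single libraries. It was 1423 without untreated replicate 1, and 328 and 403 without untreated replicates 2 and 3. It was 375, 405 and 586 without DCA replicates 1, 2 and 3; DESeq2 called 1091.

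Stress genes also rose in AKPT with DCA. In the list of endoplasmic reticulum stress and the integrated stress response 6 of 23 genes rose and 0 fell, or 7 and 1 when adjusted over the list alone (adjusted p = 0.00167; adjusted p = 0.102 with an estimated correlation). They included the lipoprotein receptor Vldlr (1.32-fold, adjusted p = 0.00161), Chac1, which degrades glutathione (1.33-fold, adjusted p = 0.0027), and asparagine synthetase, Asns (log2 0.33, adjusted p = 0.00316). Cholesterol synthesis genes fell: 4 of 25 fell and 0 rose, or 8 and 0 when adjusted over the list alone (adjusted p = 0.00489; adjusted p = 0.550 with an estimated correlation). Idi1 (ENSMUSG00000058258), an isomerase of the mevalonate pathway, went from 188 ± 2.95 to 142 ± 6.40 CPM (n = 3; 1.33-fold lower, adjusted p = 0.000932), and the sterol carrier Stard4 was 1.24-fold lower (adjusted p = 0.00133). Of 9 gastric and squamous markers 2 fell and 0 rose, or 3 and 0 when adjusted over the list alone (adjusted p = 0.0127; adjusted p = 0.395 with an estimated correlation). They were the keratin Krt6a (1.19-fold lower, adjusted p = 0.0132) and the annexin Anxa10 (1.35-fold lower, adjusted p = 0.0176). The cholesterol list lost its call without untreated replicate 2 (adjusted p = 0.134), and the gastric and squamous list without untreated replicate 2 (0.106) and DCA replicate 1 (0.0539). Krt6a lost its call without untreated replicate 2 (0.156), DCA replicate 1 (0.0555) and DCA replicate 2 (0.0976). Anxa10 lost it without untreated replicates 2 (0.0837) and 3 (0.0590) and DCA replicates 1 (0.0790) and 3 (0.101). In all 5 lists were called in AKPT, 0 of them with an estimated correlation. By fry 4 of 30 lists were called, but neither cholesterol synthesis (adjusted p = 0.142) nor the gastric and squamous markers (0.0769). It did call the enteroendocrine markers, downward (adjusted p = 0.0241), which camera did not. Without untreated replicate 1 camera called 8 lists at the preset correlation.

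The bile acid response list did not move as a group in AKPT (1 of 11 rose and 1 fell, or 1 and 2 when adjusted over the list alone; adjusted p = 0.888). Abcc3 (ENSMUSG00000020865), which exports bile acids and conjugates, rose from 177 ± 7.85 to 235 ± 12.7 CPM (n = 3; 1.33-fold, adjusted p = 4.22e-05). Slc10a2, the apical bile acid uptake transporter of the ileum, fell from 47.6 ± 1.85 to 35.2 ± 3.02 CPM (n = 3; 1.35-fold lower, adjusted p = 0.0259). Slc10a2 lost its call without untreated replicates 2 (adjusted p = 0.120) and 3 (0.104) and DCA replicates 1 (0.126) and 2 (0.113). The nuclear bile acid receptor gene Nr1h4 had 1 to 14 counts per library over all 12 libraries, Slc51a 0 to 4 and Slc51b 0 to 1, against a floor of 3 counts. The floor was 0.128 CPM at the mean library total. These 3 genes had too few counts to be tested, so a fall or a small change in them could not be seen, and none of them stood above 0.591 CPM in any library. The membrane receptor gene Gpbar1 had 21 to 77 counts per library and did not pass the test in AKPT (-0.20, adjusted p = 0.722) or in KPN (-0.02, adjusted p = 0.993).

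Genes of matrix remodelling went both ways in AKPT with DCA, 5 of 18 higher and 2 lower, or 6 and 6 when adjusted over the list alone (adjusted p = 0.289). Itgb4 (ENSMUSG00000020758), the integrin of hemidesmosomes, rose from 246 ± 9.06 to 331 ± 11 CPM (n = 3; 1.34-fold, adjusted p = 2.1e-05). The urokinase Plau rose 1.36-fold (adjusted p = 0.000795) and the laminin chain Lama3 rose 1.35-fold (adjusted p = 0.00103). In the fetal-like and regenerative list 3 of 17 rose and 4 fell, or 5 and 4 when adjusted over the list alone (adjusted p = 0.715). Osteopontin, Spp1, was 1.34-fold lower (adjusted p = 0.00177) and Anxa1 1.21-fold lower (adjusted p = 0.00498). Among YAP/TAZ targets 3 of 17 rose and 2 fell, or 6 and 2 when adjusted over the list alone (adjusted p = 0.218). Of these, Ccn2 was 1.29-fold higher (adjusted p = 0.00412), while Edn1 was 1.63-fold lower (adjusted p = 0.00151) and Ereg 1.26-fold lower (adjusted p = 0.00353). In the NRF2 list, 1 of 22 rose and 1 fell, or 2 and 1 when adjusted over the list alone (adjusted p = 0.373). The quinone reductase Nqo1 fell 1.27-fold (adjusted p = 0.0132), a call lost without untreated replicates 2 (adjusted p = 0.103) and 3 (0.0870) and DCA replicates 1 (0.0763) and 2 (0.0524). Apcdd1, a Wnt inhibitor, rose 1.57-fold (adjusted p = 0.00233) in a Wnt list with 2 of 13 higher and 2 lower, or 3 and 2 when adjusted over the list alone (adjusted p = 0.762). Pmaip1, which promotes apoptosis, was 1.27-fold lower (adjusted p = 0.00101) in a p53 list with 1 of 18 higher and 1 lower, or 2 and 1 when adjusted over the list alone (adjusted p = 0.697). Id2 rose 1.31-fold (adjusted p = 0.00117) in a TGF-beta list with 1 of 17 higher and 1 lower by both adjustments (adjusted p = 0.289).

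Proliferation lists did not pass by camera in AKPT, nor did the cell type lists other than the gastric and squamous markers. In the G2/M list 0 of 22 genes were called by edgeR, over all genes or adjusted over the list alone (adjusted p = 0.1), and Mki67 stood at 468 ± 22.8 and 478 ± 30.8 CPM (n = 3; adjusted p = 0.833). DNA replication had 1 of 24 higher and 1 lower by both adjustments (adjusted p = 0.289). Intestinal stem cell markers had 0 of 13 higher and 1 lower, or 1 and 4 when adjusted over the list alone (adjusted p = 0.218). Lgr5 stood at 24.0 ± 3.95 and 25.7 ± 2.15 CPM (n = 3; adjusted p = 0.661). Notch targets had 1 of 13 higher, or 2 higher and 1 lower when adjusted over the list alone (adjusted p = 0.888). Hes1 stood at -0.02 (adjusted p = 0.895). Of 16 immediate early and heat shock genes 2 fell, or 1 rose and 3 fell when adjusted over the list alone (adjusted p = 0.168). RAS/MAPK output had 1 of 19 higher, or 5 higher and 1 lower when adjusted over the list alone (adjusted p = 0.1). Fatty acid oxidation had 1 of 19 higher, or 3 and 1 (adjusted p = 0.521). Oxidative phosphorylation had 0 of 24 called by both adjustments (adjusted p = 0.762) and interferon response 0 of 13, or 1 lower when adjusted over the list alone (adjusted p = 0.715). The epithelial-mesenchymal transition list had 1 of 9 higher by both adjustments (adjusted p = 0.226). Markers of enterocytes had 1 of 7 higher by both adjustments (adjusted p = 0.744), of goblet cells 1 of 9 lower by both (0.242), and of immune cells 1 of 5 lower by both (0.218). Paneth and deep crypt secretory markers had 0 of 3 called, or 2 higher and 1 lower when adjusted over the list alone (0.888), and enteroendocrine markers 0 of 2, or 1 lower (0.102). Tuft cell markers had 0 of 3 called (0.645) and endothelial markers 0 of 2 (0.888), by both adjustments. The fibroblast list could not be tested: its 14 genes held 4 to 16 counts per library in all. Across all genes 2974 had an unadjusted p under 0.05 in this comparison. The lists whose median, mean and test differed in sign were bile acid response (median -0.06, mean -0.002, upward), enterocytes (-0.03, -0.07, upward), fetal-like epithelium (0.08, -0.03, upward) and matrix proteases (0.001, -0.09, upward).

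In KPN organoids DCA raised genes of cholesterol synthesis and of the NRF2 response to oxidative stress. Of 25 cholesterol synthesis genes 2 rose and 0 fell, and 15 rose when adjusted over the list alone (adjusted p = 2.19e-16; adjusted p = 0.144 with an estimated correlation). Insig1 (ENSMUSG00000045294), a regulator of sterol synthesis, went from 140 ± 0.946 to 174 ± 9.81 CPM (n = 3; 1.24-fold, adjusted p = 0.0026) and lanosterol synthase, Lss, rose 1.22-fold (adjusted p = 0.00645). Of 22 NRF2 genes 3 rose and 0 fell, and 12 rose when adjusted over the list alone (adjusted p = 2.19e-16; adjusted p = 0.121 with an estimated correlation). These were Gclc, the enzyme that limits glutathione synthesis (136 ± 5.44 to 171 ± 0.545 CPM, n = 3; adjusted p = 0.00152), sulfiredoxin, Srxn1 (61.1 ± 3.08 to 80.1 ± 3.15 CPM, n = 3; adjusted p = 0.0016), and Nqo1 (35.2 ± 1.05 to 48.0 ± 3.38 CPM, n = 3; adjusted p = 0.0181). Endoplasmic reticulum stress genes had 0 of 23 called, and 5 higher when adjusted over the list alone (adjusted p = 0.0236, upward; adjusted p = 0.144 with an estimated correlation). The NF-kB list had 0 of 22 called by either adjustment and a median of -0.10 (adjusted p = 0.0108, downward; adjusted p = 0.547 with an estimated correlation). Lss lost its call without untreated replicate 2 (adjusted p = 0.0564) and DCA replicates 1 (0.0682) and 2 (0.0920). The endoplasmic reticulum stress list lost its call without untreated replicates 2 (0.0574) and 3 (0.143) and DCA replicates 1 (0.0596) and 3 (0.05). The NF-kB list lost it without untreated replicate 3 (0.0597) and DCA replicate 1 (0.0776) and by fry (0.438). The count of 4 lists, 0 with an estimated correlation and 3 by fry, was 2 without untreated replicate 3 and 7 without untreated replicate 1 or DCA replicate 2.

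DCA changed 22 genes in KPN, 10 higher and 12 lower, and 0 of them by edgeR at 2-fold or more; 1089 genes had an unadjusted p under 0.05. Several of the genes that fell host small nucleolar RNAs in their introns. Snhg12 (ENSMUSG00000086290) went from 34.5 ± 2.79 to 20.4 ± 1.08 CPM (log2 -0.76, SE 0.0842, adjusted p = 2.06e-05). Zfas1 (ENSMUSG00000074578) went from 85.5 ± 9.34 to 56.1 ± 0.698 CPM (-0.61, SE 0.0693, adjusted p = 2.06e-05). Snhg5 fell by 0.53 (SE 0.0681, adjusted p = 0.000154) and Snhg1 by 0.46 (SE 0.0697, adjusted p = 0.00118; SD and SE, n = 3). Tcim (-0.49, adjusted p = 0.0275) and the small GTPase Rhob (-0.43, adjusted p = 0.0275) also fell. The largest rises were those of the myelin gene Pmp22 (0.63, SE 0.115, adjusted p = 0.0102), Nqo1 (0.45, SE 0.0842), Tsku (0.40, adjusted p = 0.0234), Sec24d, a coat protein of transport vesicles (0.40, adjusted p = 0.0454), Srxn1 (0.39, SE 0.0612) and Psca (0.39, adjusted p = 0.0275). Mki67 stood at 365 ± 25.3 and 365 ± 21.9 CPM (n = 3; adjusted p = 0.996), Hes1 at 0.06 (adjusted p = 0.839) and Lgr5 at 0.15 (adjusted p = 0.798).

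Of these 12 genes, Snhg12, Zfas1, Snhg5, Snhg1 and Srxn1 kept the call without each of the 6 KPN libraries. Tcim and Rhob lost it without untreated replicates 1, 2 and 3 and DCA replicates 1 and 2 (adjusted p = 0.0568 to 0.301). Pmp22 lost it without untreated replicates 1 and 2 and DCA replicates 1 and 3 (0.0622 to 0.111). Nqo1 lost it without untreated replicates 1, 2 and 3 and DCA replicates 1 and 3 (0.0810 to 0.206), and Tsku without each of the 6 (0.0857 to 0.118). Sec24d lost it without untreated replicates 1 and 3 and DCA replicates 1 and 3 (0.166 to 0.295) and with library totals (0.0796) or the replicate number as a block (0.0877), and Psca without untreated replicates 2 and 3 and DCA replicates 1 and 3 (0.110 to 0.281). The count of 22 genes was 13 without untreated replicate 1 or 2 and 11 without DCA replicate 1. DESeq2 called 47, and 64 were called without a filter on low counts. The other 26 lists had 0 genes called by edgeR, against 2 higher and 4 lower when adjusted over each list alone, and camera adjusted p from 0.0828 to 0.918. Among those 26, median, mean and test differed in sign for bile acid response (median 0.06, mean -0.02, upward), fetal-like epithelium (-0.01, 0.03, upward), gastric and squamous markers (-0.01, 0.03, downward) and Wnt targets (0.01, 0.01, downward).

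**Figure D2:**
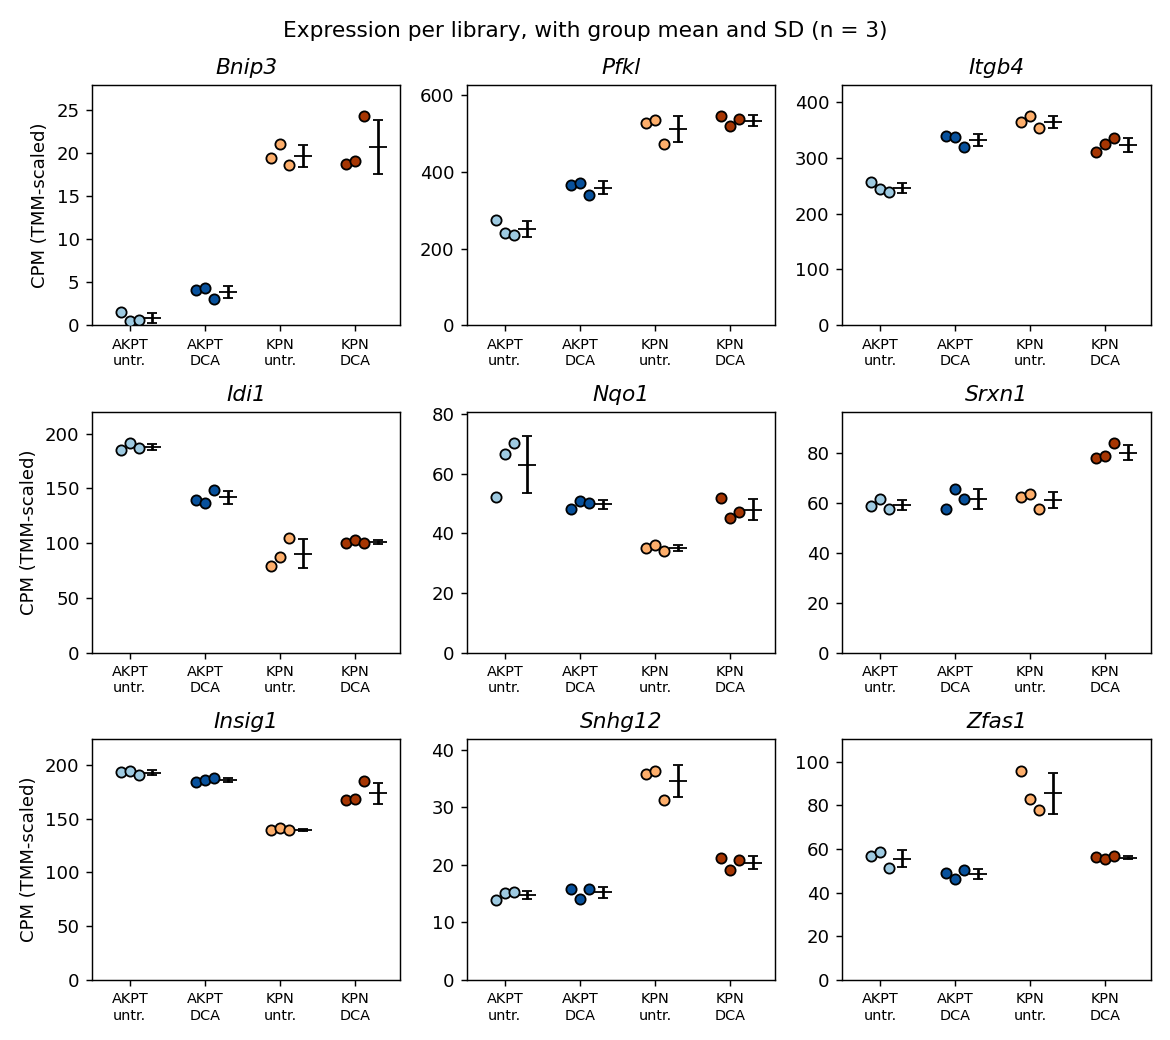
CPM, counts scaled to library size (vertical axes, from 0), of 9 genes chosen to show the DCA responses; each point is 1 library, and the bar beside each group is its mean with the SD (n = 3). Pfkl and Itgb4 are higher and Idi1 lower with DCA in AKPT, and Srxn1 and Insig1 are higher and Snhg12 and Zfas1 lower with DCA in KPN.

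The DCA responses of the genotypes were compared gene by gene with a test of the difference. The responses differed in 246 genes, 120 more positive and 126 more negative in KPN. The mitophagy receptor Bnip3 (ENSMUSG00000078566) went from 0.874 ± 0.580 to 3.87 ± 0.657 CPM in AKPT and stood at 19.7 ± 1.29 and 20.7 ± 3.10 CPM in KPN (n = 3; difference of log2 fold changes -2.06, SE 0.333, adjusted p = 0.00826). Glycolysis and hypoxia genes had more negative responses in KPN: 6 of 22 were called more negative and 0 more positive, or 17 and 0 when adjusted over the list alone (adjusted p = 5.01e-17; adjusted p = 0.414 with an estimated correlation). Cholesterol synthesis genes had more positive responses in KPN, 6 of 25 and 0 negative, or 15 and 0 when adjusted over the list alone (adjusted p = 3.03e-13; adjusted p = 0.414 with an estimated correlation). NRF2 genes also had more positive responses in KPN, 2 of 22 and 0 negative, or 5 and 1 when adjusted over the list alone (adjusted p = 0.00131; adjusted p = 0.574 with an estimated correlation).

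Itgb4 had the smallest p of the named genes (difference -0.60, SE 0.0712, adjusted p = 9.7e-05); its level was 364 ± 10.7 CPM in untreated KPN and 323 ± 12.7 with DCA (n = 3). Of the named genes called with DCA in AKPT, 15 of 58 also passed the test of the difference, and of those called in KPN 7 of 15 did. The remaining 43 and 8 were not shown to respond differently. Among genes with at least 5 CPM in a group, the most negative differences after Bnip3 were those of Chdh (-1.36, adjusted p = 0.0242), Angptl6 (-1.26, adjusted p = 0.0197), Fbln2 (-1.17, adjusted p = 0.0363) and Synpo (-1.15, adjusted p = 0.0394). By the same limit the most positive were those of the sialyltransferase St3gal5 (1.31, adjusted p = 0.0303), the small GTPase Gem (1.254, adjusted p = 0.0262), Dtwd2 (1.11, adjusted p = 0.0134), Bmper (1.10, adjusted p = 0.0306) and U90926 (1.09, adjusted p = 0.00501). Bnip3 and U90926 kept the call without each of the 12 libraries and Dtwd2 lost it only without untreated KPN replicate 2 (adjusted p = 0.0546). The other 7 each lost it without 4 to 9 of the 12 libraries. All 7 lost it without AKPT DCA replicate 1 (0.0542 to 0.107) and untreated KPN replicate 2 (0.0656 to 0.143). All but Angptl6 lost it without AKPT DCA replicate 2 (0.0516 to 0.114), KPN DCA replicate 1 (0.0589 to 0.101) and KPN DCA replicate 2 (0.0513 to 0.0846), and all but Fbln2 without untreated AKPT replicate 2 (0.0624 to 0.128). St3gal5, Gem, Angptl6 and Fbln2 lost it without AKPT DCA replicate 3 (0.0508 to 0.0653), and St3gal5, Gem, Fbln2 and Synpo without KPN DCA replicate 3 (0.0551 to 0.0786). Gem, Fbln2 and Synpo lost it without untreated AKPT replicate 3 (0.0805 to 0.109), St3gal5 and Bmper without untreated KPN replicate 3 (0.0589 to 0.0614), and Fbln2 without untreated KPN replicate 1 (0.0815). The count of 246 was 828, 72 and 102 without untreated AKPT replicates 1, 2 and 3, and 43, 92 and 157 without AKPT DCA replicates 1, 2 and 3. It was 154, 52 and 420 without untreated KPN replicates 1, 2 and 3, and 68, 119 and 160 without KPN DCA replicates 1, 2 and 3. DESeq2 called 512, and 601 were called without a filter on low counts.

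Immediate early and heat shock genes were the fourth list with a difference, with 0 of 16 genes called by edgeR and 3 more positive and 1 more negative when adjusted over the list alone (adjusted p = 0.0428, more positive in KPN; adjusted p = 0.447 with an estimated correlation). The list was fixed to stand for RNA handling, so handling cannot be told apart here from a response to DCA. That list lost its call without untreated AKPT replicate 2 (adjusted p = 0.0667), AKPT DCA replicate 1 (0.107), untreated KPN replicates 2 (0.0582) and 3 (0.235) and KPN DCA replicate 3 (0.0832), and with a filter at 1 CPM (0.0643). By fry 0 of the 30 lists differed, with adjusted p of 0.0713 for cholesterol synthesis, 0.0874 for glycolysis and hypoxia, 0.0874 for immediate early and heat shock genes and 0.207 for NRF2. The other 26 lists had 1 gene more positive and 7 more negative, or 24 and 17 when adjusted over each list alone, with camera adjusted p from 0.0810 to 0.990. The signs of median, mean and test differed in 8 of those lists: bile acid response (median 0.01, mean -0.02, upward), enterocytes (0.03, -0.08, downward), epithelial-mesenchymal transition (0.02, -0.01, downward), fetal-like epithelium (-0.03, 0.06, downward), matrix proteases (0.04, 0.07, downward), RAS/MAPK output (-0.06, 0.002, downward), TGF-beta targets (-0.04, 0.07, downward) and tuft cells (-0.15, 0.04, downward).

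The calls of the DCA responses overlapped in few genes. Sec24d and Tsku were higher in both genotypes, where 0.322 genes would be shared if the calls were independent (Fisher's exact p = 0.0392). Rhob, Aldh1a3, 1110038B12Rik and AC100212.9 were lower in both, against 0.359 (p = 0.000323, Fisher's exact test, two-sided). That test takes genes as independent, and both responses share 1 estimate of the spread, so its p-values are rough. Of the 6 libraries left out in turn in KPN, Tsku lost its call there without 6, Rhob without 5 and Sec24d without 4. Over 10173 genes with a mean of at least 5 CPM the log2 fold changes of the responses correlated at r = -0.038 (Spearman's rho = -0.038), across genes, which are not independent replicates. Of the 22 genes called in KPN 18 had the same sign in AKPT, and of the 903 called in AKPT 428 had the same sign in KPN.

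**Figure D3:**
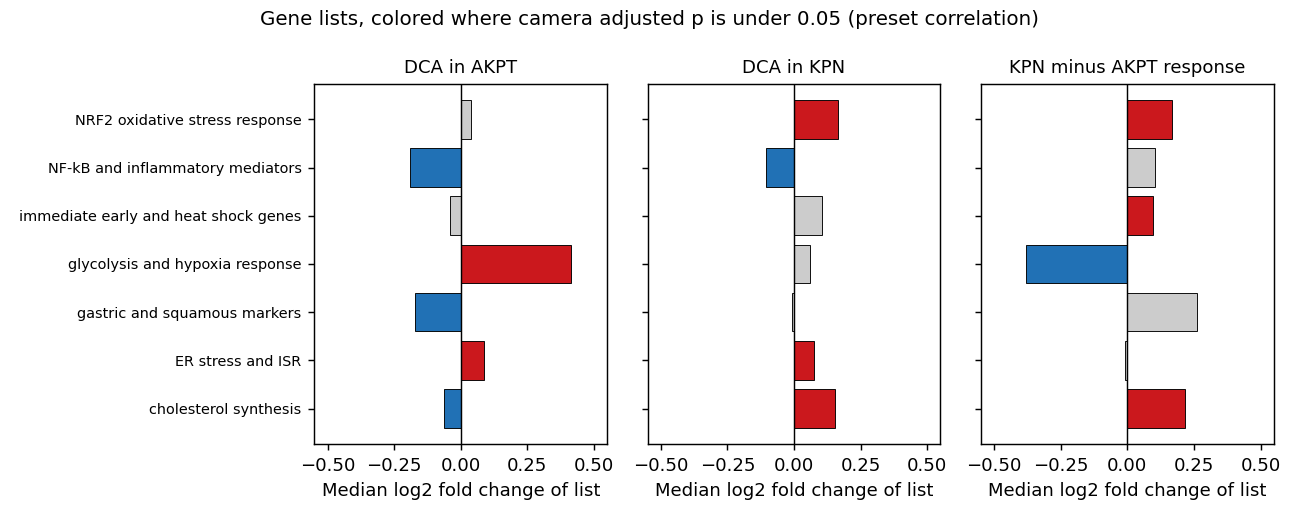
Median log2 fold change (horizontal axis) of 7 gene lists with DCA in AKPT, with DCA in KPN, and as the KPN response minus the AKPT response; red bars are lists called upward and blue bars lists called downward by camera at the preset correlation, and grey bars were not called. Glycolysis and hypoxia stands at 0.41 in AKPT and 0.06 in KPN, and cholesterol synthesis at -0.06 and 0.15.

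Without DCA, KPN organoids had more transcripts of glycolysis and the hypoxia response and less of cholesterol synthesis than AKPT. All 22 glycolysis and hypoxia genes were higher in KPN by both adjustments (adjusted p = 1.51e-32; 0.0446 with an estimated correlation). Among them were Gpi1 at 785 ± 43.8 against 358 ± 18.0 CPM (n = 3; 2.19-fold), P4ha1 at 2.70-fold and aldolase, Aldoa, at 2.16-fold. All 25 cholesterol synthesis genes were lower by both adjustments (adjusted p = 6.24e-22; 0.0446 with an estimated correlation). Among them were the demethylase Cyp51 at 314 ± 12.6 against 587 ± 36.8 CPM (n = 3; 1.87-fold lower), Hsd17b7 (2.47-fold lower) and squalene epoxidase, Sqle (1.67-fold lower). Among genes with at least 5 CPM in the higher group, the largest rises were those of the enolase Eno2 (ENSMUSG00000004267) at 37.8 ± 2.28 against 1.55 ± 0.835 CPM (24.2-fold, log2 SE 0.284). Next came Bnip3 (4.48, SE 0.241), the lectin Clec2f (4.43, SE 0.247), Ifitm1 (3.50, SE 0.110), the peptide hormone adrenomedullin, Adm (3.42, SE 0.273), and Selenbp1 (3.22, SE 0.339), with adjusted p from 1.06e-18 to 5.38e-05 (n = 3).

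Transcripts lower in KPN included the matrix genes Timp3 (log2 -4.85, SE 0.565, adjusted p = 0.000101) and Prelp (-4.34, SE 0.655, adjusted p = 0.000276), the receptor Gpr55 (-4.46, SE 0.342, adjusted p = 8.66e-11) and the scaffold Homer2 (-6.34, SE 0.328, adjusted p = 2.97e-14; 7.38 ± 0.965 against 0.0863 ± 0.0449 CPM, n = 3). Sprr1b had 415 counts over the 3 untreated AKPT libraries and 2 over those of KPN, a ratio of 209 (95% exact counting interval 57.4 to 1730). The chitinase-like Chil4 had 404 and 3, a ratio of 135 (46.0 to 660). In all 7467 genes differed, 3592 higher and 3875 lower in KPN, of which 1354 differed at least 2-fold (903 higher and 451 lower). The 12 named genes kept their calls without each of the 6 libraries.

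Transcripts of the bile acid response list were lower in untreated KPN: of 11 measured genes 1 was higher and 8 lower by both adjustments (adjusted p = 1.77e-05; 0.0217 with an estimated correlation). The transporters Slc10a2 (6.76 ± 1.20 against 47.6 ± 1.85 CPM, n = 3; 7.06-fold lower, adjusted p = 3.14e-12), Abcb1a (7.40-fold lower) and Abcg2 (2.07-fold lower) were among them. In endoplasmic reticulum stress genes 13 of 23 were higher and 4 lower by both adjustments (adjusted p = 6.15e-07; 0.0167 with an estimated correlation). They included the stress factor Ddit3 at 34.4 ± 3.17 against 7.14 ± 1.09 CPM (n = 3; 4.81-fold), Asns (2.08-fold) and Sesn2 (1.92-fold). Gastric and squamous markers were lower, 6 of 9 with 0 higher, or 6 and 1 when adjusted over the list alone (adjusted p = 2.02e-06; 0.0470 with an estimated correlation). They included involucrin, Ivl (4.69-fold lower), Krt6a (2.09-fold lower) and Krt14 (1.78-fold lower).

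The other lists called between untreated genotypes lost the call with an estimated correlation. DNA replication genes were lower, 18 of 24 by both adjustments (adjusted p = 6.15e-07; adjusted p = 0.308 with an estimated correlation), among them cyclin E1, Ccne1 (2.37-fold lower), and Pcna (1.72-fold lower). G2/M genes were lower, 14 of 22 by both adjustments (0.0159; adjusted p = 0.459 with an estimated correlation). NF-kB mediators had 12 of 22 lower and 3 higher by both adjustments (0.000891; adjusted p = 0.336 with an estimated correlation), led by the chemokine Cxcl5 (2.81-fold lower). Fetal-like genes had 9 of 17 lower and 1 higher by both adjustments (0.00424; adjusted p = 0.308 with an estimated correlation), led by Ly6d (2.52-fold lower). Stem cell markers had 7 of 13 lower, or 8 lower and 1 higher when adjusted over the list alone (0.0218; adjusted p = 0.186 with an estimated correlation), with Hopx 7.64-fold and Olfm4 8.69-fold lower. Goblet cell markers had 6 of 9 lower and 2 higher by both adjustments (0.0432; adjusted p = 0.459 with an estimated correlation), with Clca1 14.0-fold lower. Immediate early and heat shock genes, the list that stands for RNA handling, had 10 of 16 lower and 3 higher by both adjustments (0.0446; adjusted p = 0.308 with an estimated correlation). Targets of p53 had 9 of 18 higher and 4 lower by both adjustments (0.0376; adjusted p = 0.336 with an estimated correlation), with the cell cycle inhibitor Cdkn1a 4.44-fold and Gadd45a 3.59-fold higher. The labels give Trp53 fl/fl in both genotypes, so changes in this list do not by themselves show p53 activity. RAS/MAPK output had 11 of 19 higher and 1 lower by both adjustments (0.0446; adjusted p = 0.336 with an estimated correlation), with the phosphatase Dusp6 1.63-fold higher.

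Calls of 5 of these lists were lost when single libraries were left out in turn. The G2/M list was not called without untreated AKPT replicate 1 (adjusted p = 0.0572), nor p53 targets without untreated AKPT replicate 3 (0.0612). Goblet markers were not called without untreated AKPT replicate 3 (0.106) or untreated KPN replicates 1 (0.0611) or 3 (0.0696), nor heat shock genes without untreated KPN replicates 2 (0.0516) or 3 (0.0902). RAS/MAPK output was not called without untreated AKPT replicates 1 (0.0572), 2 (0.0527) or 3 (0.0646) or untreated KPN replicates 2 (0.0588) or 3 (0.0555). With a filter at 1 CPM goblet markers (0.0891), heat shock genes (0.0753) and RAS/MAPK output (0.0528) were not called, nor was RAS/MAPK output with the replicate number as a block (0.0531). The count of 14 lists was 5 with an estimated correlation and 20 by fry.

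Among the 16 lists not called between untreated genotypes (adjusted p = 0.101 to 0.892), 54 genes were higher and 50 lower in KPN, or 56 and 48 when adjusted over each list alone. Notch targets had 3 of 13 higher and 3 lower by both adjustments (adjusted p = 0.869), with Hes6 1.57-fold and Notch3 1.37-fold higher and the ligand Jag1 1.40-fold lower. TGF-beta targets had 10 of 17 higher and 4 lower by both adjustments (adjusted p = 0.158), with Skil 1.71-fold higher and Id1 1.90-fold lower. In the YAP/TAZ list 8 of 17 were higher and 3 lower by both adjustments (adjusted p = 0.158), with the receptor kinase Axl 8.36-fold higher and Edn1 5.51-fold lower. In the epithelial-mesenchymal transition list 3 of 9 were higher and 3 lower by both adjustments (adjusted p = 0.106), with vimentin, Vim, at 192 ± 8.82 against 50.8 ± 2.53 CPM (n = 3) and the collagen Col4a2 1.52-fold lower. Immune cell markers had 1 of 5 higher and 2 lower by both adjustments (adjusted p = 0.869), with Cd68 2.87-fold higher, Cd14 1.82-fold lower and Ptprc at 0.243 ± 0.0624 against 0.906 ± 0.142 CPM (n = 3). Median, mean and test differed in sign for fatty acid oxidation (median 0.08, mean -0.05, upward), interferon response (0.06, -0.05, upward) and matrix proteases (0.11, -0.04, upward).

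With DCA the genotypes differed in 6340 genes, 3113 higher and 3227 lower in KPN, of which 911 differed at least 2-fold (646 higher and 265 lower). Clec2f (log2 3.94, SE 0.237), Ifitm1 (3.82, SE 0.112) and Eno2 (2.89, SE 0.240) were the highest with at least 5 CPM in the higher group. Homer2 (-5.91, SE 0.303), the keratin Krt4 (-4.02, SE 0.140; 9.90 ± 1.18 against 161 ± 24.3 CPM) and the intestinal transcription factor Isx (-3.79, SE 0.170) were the lowest by that limit. Adjusted p ran from 5.29e-19 to 5.81e-06 (SD and SE, n = 3). Glycolysis and hypoxia genes stayed higher in KPN, 20 of 22 by both adjustments (adjusted p = 4.62e-23; adjusted p = 0.0952 with an estimated correlation). Endoplasmic reticulum stress genes were higher too, 15 of 23 with 1 lower, or 16 and 2 when adjusted over the list alone (9.3e-08; 0.0068 with an estimated correlation). So were p53 targets, 9 of 18 with 2 lower, or 10 and 2 (0.00284; adjusted p = 0.231 with an estimated correlation). Cholesterol synthesis genes were lower, 22 of 25 by both adjustments (1.9e-13; adjusted p = 0.1 with an estimated correlation). So were bile acid genes, 8 of 11 with 1 higher by both adjustments (3.29e-07; 0.0068 with an estimated correlation). Gastric and squamous markers were lower in 5 of 9 and higher in 2 by both adjustments (3.22e-06; adjusted p = 0.0753 with an estimated correlation).

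DNA replication genes were lower with DCA too, 18 of 24 or 20 when adjusted over the list alone (3.68e-10; adjusted p = 0.194 with an estimated correlation), as were G2/M genes, 18 of 22 or 19 (4.8e-05; adjusted p = 0.277 with an estimated correlation). Fetal-like genes had 10 of 17 lower and 3 higher, or 11 and 3 when adjusted over the list alone (0.000268; adjusted p = 0.194 with an estimated correlation). NF-kB mediators had 12 of 22 lower and 5 higher, or 13 and 5 when adjusted over the list alone (0.0057; adjusted p = 0.352 with an estimated correlation). Goblet cell markers had 5 of 9 lower and 1 higher by both adjustments (0.0395; adjusted p = 0.468 with an estimated correlation), and stem cell markers 8 of 13 lower and 2 higher by both (0.0440; adjusted p = 0.206 with an estimated correlation). Stem cell markers lost the call without AKPT DCA replicate 3 (0.0554) and KPN DCA replicate 3 (0.0530) and with a filter at 1 CPM (0.0640). Goblet markers lost it without KPN DCA replicate 3 (0.0627) and with that filter (0.110). The count of 12 lists was 2 with an estimated correlation and 23 by fry. The other 18 lists had 76 genes higher and 54 lower, or 77 and 57 when adjusted over each list alone (camera adjusted p = 0.0519 to 0.779). Signs differed for immune markers (median -0.43, mean 0.08, upward) and Paneth markers (0.57, -0.08, downward).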

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

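The tests of shared libraries, KPN material, culture state, matched random lists and ribosomal protein genes given here were chosen only after the results were seen.

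The DCA responses of the genotypes differed in 246 genes by the test of the difference. Of 100 relabellings of DCA within each genotype 4, the real one included, called as many, and the highest other called 299. The 3 others that called as many were among the 11 that kept the AKPT groups whole. Chance labels in KPN were thus not excluded. The 88 that broke the AKPT groups called 4 at most. They put any DCA response of AKPT into the spread within groups, which lowers their counts, so they do not exclude chance either. The count did not need the real KPN labels and does not by itself show a response in KPN.

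The lists with a difference were glycolysis and hypoxia (camera adjusted p = 5.01e-17), cholesterol synthesis (3.03e-13), NRF2 (0.00131) and immediate early and heat shock genes (0.0428), at the preset correlation. None kept the call with an estimated correlation (adjusted p = 0.414, 0.414, 0.574 and 0.447 in that order), and fry called 0 of 30 lists. With more negative responses in KPN than in AKPT, the named genes were Bnip3 (-2.06), Chdh (-1.36), Angptl6 (-1.26), Fbln2 (-1.17), Synpo (-1.15), Snhg12 (-0.81), Itgb4 (-0.60), Plau (-0.56), Tcim (-0.55), Lama3 (-0.52), Snhg5 (-0.47), Asns (-0.46), Pfkl (-0.45), Vldlr (-0.43), Zfas1 (-0.42), P4ha1 (-0.41), Gpi1 (-0.40) and Abcc3 (-0.30). With more positive responses in KPN they were St3gal5 (1.31), Gem (1.254), Dtwd2 (1.11), Bmper (1.10), U90926 (1.09), Nqo1 (0.79), Idi1 (0.57), Stard4 (0.47), Insig1 (0.36), Ereg (0.36), Srxn1 (0.34) and Sc5d (0.33). Values are differences of log2 fold changes, KPN minus AKPT.

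With DCA the AKPT libraries lay nearer to KPN: 756 of the 903 genes called in AKPT (83.7%) moved toward KPN on an axis that weighs both AKPT groups alike, and 73% on an axis with the DCA group alone, which shared noise works against. The untreated AKPT libraries enter both the DCA response and the untreated genotype contrast, which alone gave r = 0.501 in simulated data with nothing changed, against 0.628 observed over 10173 genes. The covariance was 0.00532 in those data against 0.0578. After the mean noise per gene of the untreated AKPT libraries was taken off, 89.3% of the observed value stayed. Without each AKPT library in turn 75.9% to 91.0% stayed. This argues against noise that is independent between genes. A joint deviation of the untreated libraries along the genotype axis was not taken off. Against an axis without them, untreated replicates 1, 2 and 3 deviated at r = 0.315, -0.436 and 0.041. KPN material in the AKPT libraries would give 1 share from all genes. Genes high in KPN gave a median of 11.7% and genes high in AKPT 44.5%, a difference of 32.7 (bootstrap 95% interval over genes 22.1 to 40.8). The untreated AKPT libraries both chose these genes and entered the share, so values high there by chance would raise the 44.5%. KPN material therefore stays open. A culture state that varies without DCA stays open, as does an effect of DCA: the range of the untreated AKPT libraries along the genotype axis was 100.2% of the shift with DCA (0.214; SD of those libraries 0.107, n = 3), but 32.5% without untreated replicate 1 and 69.4% to 124.4% without each of the others.

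A set of genes that host small nucleolar RNAs was lower with DCA in KPN. Its median was -0.30 over 13 genes, of which 5 were called and 11 had a negative sign. The set was picked by name (Snhg with a number, Gas5 and Zfas1). Hosts with other names were not gathered, so the values do not cover all host genes. The called genes led to the list, so its tests rest on the 8 members that were not called, with a median of -0.18 and 6 negative signs. Of 10000 random lists matched to these for transcript length, GC content and expression 0.46% had a median as low, which argues against those traits as the source. Ribosomal protein genes had a median of -0.08, which was 43.2% of that of the 8 (42.0% with RLE factors, 46.3% with library totals), but the difference of medians was -0.105 with a bootstrap 95% interval of -0.222 to 0.254, so a general fall of such messages stays open. Reads of the small RNAs themselves stay open too, because the strand setting and read handling are not known. Without DCA, 9 of the 13 host genes were called higher in KPN than in AKPT and 1 lower, with a median of 0.62. With DCA the calls were again 9 higher and 1 lower, with a median of 0.41.

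For the pairwise comparisons the 10 splits of 6 libraries into 3 and 3 were too few to exclude chance. With the real split, the only 1 of the 10 that called as many, the counts were 903 for DCA in AKPT (highest other 1), 22 for DCA in KPN (highest other 1), 7467 for untreated genotypes (highest other 0) and 6340 for genotypes with DCA (highest other 0).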

How the results depend on the processing

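No test in this part was chosen only after the result was seen; the alternatives were fixed before the data were examined.

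With 3 libraries per group, counts of called genes moved with single libraries, most of all for DCA in AKPT and for the difference; the cause was not tested. Genes called with DCA in AKPT numbered 291 at an adjusted p under 0.01, 76 at an absolute log2 fold change of at least 1 and 328 to 1423 over the libraries left out. In KPN they numbered 12 and 0 at those settings, 64 without a filter on low counts, 47 by DESeq2 and 11 to 19 over the libraries left out. For the difference they numbered 33 and 26, 601 without a filter, 512 by DESeq2 and 43 to 828. At a log2 fold change of at least 1 the genotypes differed in 1354 genes untreated (6481 to 7258 over libraries left out, without that limit) and 911 with DCA (5201 to 5848). With library totals the 7412 genes called between untreated genotypes were 4154 higher and 3258 lower in KPN, against 3592 and 3875 with TMM, and with DCA the 6328 were 3597 and 2731, against 3113 and 3227. With the replicate number as a block 793 genes were called with DCA in AKPT. Lists called with an estimated correlation numbered 0 with DCA in AKPT, 0 with DCA in KPN, 5 between untreated genotypes, 2 between genotypes with DCA and 0 for the difference; fry called 23 between genotypes with DCA and 0 for the difference. Over the libraries left out the lists called numbered 4 to 8 with DCA in AKPT, 2 to 7 in KPN, 11 to 13 untreated, 11 to 15 with DCA and 3 to 6 for the difference.

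Signs turned only for genes that were not called. For DCA in AKPT, Notch1 stood at 0.004 with RLE factors, 0 with library totals, 0.005 with DESeq2 and -0.009 to 0.021 over the libraries left out, Trp53 at -0.128 to 0.093, Hes1 at -0.034 to 0.005, Mki67 at -0.017 to 0.081 and Gpbar1 at -0.381 to 0.053. For DCA in KPN, Apc stood at -0.025 to 0.174, Tgfbr1 at -0.002 to 0.194, Trp53 at -0.116 to 0.055, Hes1 at -0.018 to 0.11, Gpbar1 at -0.168 to 0.214, and Mki67 at -0.009 with library totals and -0.049 to 0.053 over the libraries left out. Between genotypes Trp53 stood at -0.013 to 0.134 untreated and -0.088 to 0.139 with DCA, and Notch1 with DCA at 0.005 with library totals. For the difference Tgfbr1 stood at -0.066 to 0.13 and Trp53 at -0.137 to 0.085. Of 215 gene results, called or not, library totals lost the call of 4, gave a call to 1 and turned the sign of 3 that were not called. RLE factors lost 2 and turned 1, the block lost 8, and DESeq2 lost none of 214 and turned 1. Over libraries left out 1114 were the same, 237 weaker, 2 stronger and 27 reversed. Of 39 list calls 32 held by fry, 33 with a filter at 1 CPM and 38 with the block.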

Other observations

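The tests of the axis positions and the genes in this part were chosen only after the results were seen.

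The organoids of both genotypes carried squamous and intestinal transcripts side by side. The basal keratin Krt5 ran from 1145 to 2088 CPM over the 12 libraries and Krt14 from 527 to 1087, next to the simple keratins Krt8 (2598 to 3568) and Krt18 (1270 to 1922) and the intestinal genes Cdh17 (927 to 1135), Vil1 (189 to 279) and Cdx2 (37.9 to 58.0). Cdx1 stayed at or under 1.72 CPM. With DCA in AKPT Krt8 rose by 0.34 (adjusted p = 0.000158) and Krt18 by 0.35 (adjusted p = 9.57e-05).

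Transcripts of mast cell proteases were abundant in cultures in which Ptprc, a marker of blood cells, reached 1.07 CPM at most in a library. Mcpt1 was at 349 ± 28.1 CPM in untreated AKPT and 47.0 ± 2.85 in untreated KPN (n = 3; log2 -2.89, adjusted p = 1.66e-10), and Mcpt2 was lower in KPN too (-2.43, adjusted p = 9.02e-15). Mcpt8 ran from 119 to 172 CPM in all libraries and rose by 0.38 with DCA in AKPT (adjusted p = 0.00101), where Mcpt2 fell by 0.31 (adjusted p = 0.0481) and Mcpt1 stood at -0.19 (adjusted p = 0.311).

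Whether DCA moves AKPT organoids along an axis on which untreated cultures already vary could not be told from 3 libraries. Their range was 100.2% of the shift between group means, but 32.5% without untreated replicate 1. On that axis the untreated AKPT libraries lay at 0.003, -0.211 and -0.113, and those with DCA at 0.175, 0.099 and 0.047. More untreated AKPT cultures, sampled with DCA cultures from the same passage and with oxygen and density recorded, would separate a change in culture state from an effect of DCA. If DCA acts apart from culture state, Bnip3 and Pfkl would rise also in pairs alike in oxygen and density. If their rise follows culture state alone, it would be absent in such pairs.

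The fall of the host genes picked by name, with DCA in KPN, could reflect a change in transcript decay. The matched lists (0.46% as low) and ribosomal protein genes (43.2% of the median of the hosts not called) do not address that. Host transcripts in KPN cultures with translation blocked, with and without DCA, would test it: if decay tied to translation is the route, the fall of Snhg12 and Zfas1 would be lost.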
